A study of Bos taurus with 6 samples.

How the data were processed

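Amplified RNA of rFSH-treated and control cumulus cells was labelled with Cy3 and Cy5 and hybridised together on 6 Agilent arrays of bovine probes. Per the labels' protocols the RNA went through T7 linear amplification in a pair of rounds and direct chemical labelling. Per the file headers the scanner files hold spot and local background intensity on a linear scale at 532 nm (Cy3) and 635 nm (Cy5), not normalized, and the image software's mark for ignored spots, whose rule is not given in the sources used here. The authors also deposited a pair of tables of normalized log2 ratios, identical for all bovine probes. Set against the scanner values they held log2 Cy5 over Cy3, not turned for the dye swap (r between 0.976 and 0.992 per array), with column medians from -0.0202 to 0.00122; how they were normalized is not given in the sources used here. They served as an alternative.

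The scanner files gave 45220 spots per array, 43794 of them bovine probes with 1 spot each. Mean pixel intensities were corrected with normexp (offset 50, median local background) and normalized within arrays by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Control spots had weight 0 in loess and were left out afterwards, as were 18 to 64 ignored spots per array. A probe was tested where its raw signal exceeded the mean plus 2 SD of the 153 negative control spots on at least 3 arrays of the rFSH channel or of the control channel, which left 34831 probes. Each ratio was turned to rFSH over control using the dyes in the labels, both arrays of a replicate were averaged, and the 3 replicate values were tested against 0 with lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. The ratio lies within a replicate number, so the pairing is part of the test. Where a side was not above the negative controls on any array, a bound was computed per channel after loess and Aquantile, against the higher of the lowest detected signal and the probe's own. For MYH11, the named gene this concerned, this gave the fitted ratio itself, so no bound is reported.

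Gene symbols came from the platform annotation, which is old. Of the bovine probes 21790 had 1 symbol, none had several, and 22004 were unnamed here; 20068 symbols matched current RefSeq symbols, 1644 more were updated through synonyms and 78 matched neither. A gene was represented by its tested probe of highest mean intensity. Of 1146 called genes, 402 had several tested probes, and 3 had another called probe of opposite sign. Probes that were not called did not enter that count. Coordinates are not given because no genome build was named.

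The 22 gene lists, their tests, the rule for named genes and all alternatives but 4 were chosen before the data were examined; those 4 and the tests of the closing part were chosen after. Named genes were, first, the 12 largest in each direction among those with adjusted p under 0.05 and the same sign on all 6 arrays; second, up to 4 members of each list with adjusted p under 0.05 by size of ratio, whatever their sign on single arrays; and, called or not, FSHR, LHCGR, HAS2, PTGS2, TNFAIP6, PTX3, AREG, EREG, CYP19A1 and STAR. Lists were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over the 22 lists. The alternatives with a random replicate block, array weights or no replicate block used camera's preranked form, on moderated t values. There the set test changed together with the model.

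The steps were tested on simulated data with the spreads of the 34831 probes of this comparison and 200 changed probes. Of 50 probes each changed by 0.5, 1, 2 and 3 on the log2 scale, 0, 4, 37 and 46 were recovered, with 1 false call. Camera called 20 of 20 lists raised by 0.5 and 0 of 40 unchanged lists. Noise was drawn independently for each probe, so camera was not tested on correlated genes. In the data, the estimated correlation within a list reached 0.767. The simulation also changed fewer probes than were called in the data, so its recovery may not carry over. Alternatives covered background correction, normalization, filter, arrays used, pairing, weights, threshold, replicates, pixel statistic and set test. Slide as a block was not run, since no file names a slide.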

Results

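Gene expression was measured in cumulus cells, the somatic cells that surround the oocyte, taken from cumulus-oocyte complexes of Holstein cows. The complexes were matured in vitro with recombinant follicle-stimulating hormone (rFSH, 0.5 µg/mL) or without it, and the medium of both groups held 1 µg/mL estradiol. The design had 3 biological replicates, numbered 2, 3 and 4, and each was hybridised on 2 two-colour arrays with the dyes exchanged, which gave 6 arrays. Every array therefore compared rFSH-treated with control cells of the same replicate number. The labels name the control for 6 h while the culture protocol gives 22 to 24 h for both groups, so the time of the control sample, and whether the groups were matched in time, was not settled. If the times differed, each ratio below would hold the difference in time as well as that in rFSH. Between 38.3% and 83.3% of the 43794 bovine probes exceeded the negative control spots in a channel of an array, and the 3 replicates limit the precision of every ratio.

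The main comparison asked which transcripts differed between cumulus cells with and without rFSH. Transcripts of SCG2, a secretory granule protein, were 42.7-fold higher with rFSH, with a log2 ratio of 5.42 ± 0.45 (SD, n = 3). The kinase PLK2 followed at 3.98 ± 0.35 and the hyaluronan-binding matrix protein TNFAIP6 at 3.77 ± 0.18. At the other end, the scavenger receptor OLR1 had a log2 ratio of -3.86 ± 0.16 and the viral RNA sensor IFIH1 one of -3.76 ± 0.25. In limma with Benjamini-Hochberg adjustment, 1035 of 34831 tested probes were higher and 1173 were lower with rFSH. With 1 probe per gene, 509 of 13134 named genes were higher and 637 were lower.

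The 12 largest increases among named genes with the same sign on all 6 arrays also took in the chemokine receptor CXCR4 (log2 ratio 3.74), the guidance ligand SLIT3 (3.69), CAMK2N2 (3.64), an inhibitor of a calcium-dependent kinase, the gelatinase MMP9 (3.62), FAM216B (3.47), the protocadherin PCDH8 (3.25) and the secreted protein CTHRC1 (3.10). The cytochrome P450 probes CYP3A5 (3.65) and CYP3A4 (3.60) complete the group; they are paralogs, and binding of transcripts of one by the probe of the other was not excluded. The 12 largest decreases included the semaphorin SEMA6D (-3.32), the nuclear envelope protein SYNE2 (-3.18), ODF2L (-3.15), TRIM6 (-3.00), DDAH1 (-2.99), PARP9 (-2.86), HERC5 (-2.75), MSRB3 (-2.68), MYOF (-2.66) and HOPX (-2.63). Other probes of ODF2L, DDAH1 and MSRB3 lay nearer 0, up to -0.197, -0.42 and -0.35, and 1 probe of each was not called. Adjusted p values from limma for these 24 genes lay between 0.0118 and 0.0309.

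**Figure D1:**
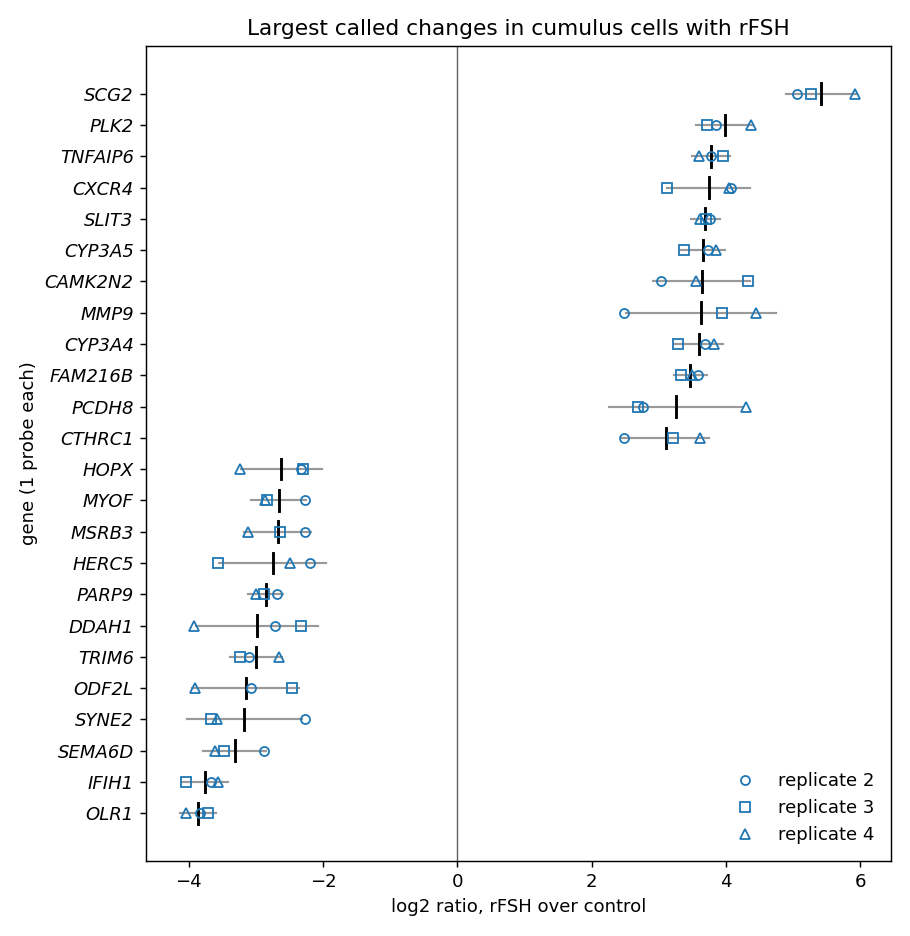
Log2 ratio of rFSH over control for the named genes with the largest called changes, 1 row per gene. Open symbols are the 3 replicates, black ticks their mean and grey lines the 95% confidence interval from limma; SCG2 lies highest at 5.42 and OLR1 lowest at -3.86.

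The count of calls rested on having all 3 replicates. Without replicate 2 or without replicate 3 no probe passed in limma, although 6875 and 7399 probes had an unadjusted p under 0.05, and without replicate 4 there were 510 higher and 677 lower probes. With median centring in place of loess 29.6% of the called probes were higher, against 46.9% in the comparison above. The share was 54.2% without background correction, 51.1% with plain subtraction of the background and 52.2% with the authors' values. The balance of directions thus depended on background correction and normalization. Of the 63 called named genes, 37 kept their call under every alternative with all replicates that tested them. Among these, CAMK2N2, FAM216B, DUSP5, CREM, GJA5 and ADAMTS1 were tested under 17 such alternatives and the others under 18. A further 11 lost the call under 1, and BTC and RRM2 under 2. Under 3 it was lost by 7, namely SPRY1 (adjusted p up to 0.298 in limma), DHCR7, B2M, HSD17B7, MYH11, ACTA2 and NR4A2. Another 6 lost it under more, as given below.

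Genes of cumulus expansion, the hyaluronan-rich swelling of the cumulus, were measured for 13 members, of which 4 rose and 1 fell. TNFAIP6 was 13.7-fold higher, the EGF-like ligand AREG rose with a log2 ratio of 3.07 ± 0.49 (SD, n = 3), the hyaluronan synthase HAS2 with 2.61 ± 0.43 and the protease ADAMTS1 with 2.22 ± 0.62, while the EGF-like ligand BTC fell by 0.83 on the log2 scale, with 1 of its 3 probes called. Adjusted over the list alone, 5 members were higher and 1 was lower. PTGS2, the inducible cyclooxygenase, had a log2 ratio of 0.57 ± 0.63 (adjusted p = 0.278) and PTX3, a hyaluronan-linked pentraxin, one of -0.64 ± 0.88 (adjusted p = 0.371), so neither difference exceeded the replicate spread in limma. The PTGS2 probe exceeded the negative controls on 4 arrays in the rFSH channel and 3 in the control channel. Its ratio thus rests on dim signal near the negative controls. The list did not shift as a whole by camera (adjusted p = 0.168), by camera with an estimated correlation (adjusted p = 0.860) or by fry (adjusted p = 0.122). Camera called it with median pixels, an alternative chosen after seeing the data (adjusted p = 0.0374). The preranked form of camera called it with the replicate as a random block (adjusted p = 8.12e-06) and unpaired, with no replicate block (adjusted p = 1.02e-07). It also did so with array weights (adjusted p = 5.28e-05), where the arrays of a dye swap counted as independent. In the preranked calls the set test changed as well as the model, so they cannot be laid to blocking, weights or pairing.

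The cAMP, protein kinase A and CREB list had the smallest camera p of the fixed lists, with 6 of 20 measured members higher and none lower. The orphan nuclear receptor NR4A1 had a log2 ratio of 2.22 ± 0.50 (SD, n = 3), the cAMP-responsive repressor CREM 1.97 ± 0.12 (its other probe 0.0271 and not called), the regulatory kinase subunit PRKAR1A 1.08 ± 0.15 and NR4A2 1.01 ± 0.17. Adjusted over the list alone, 10 were higher. Its mean log2 ratio was 0.57, and camera gave an adjusted p = 0.000922 at the preset correlation. With the correlation estimated from these replicates, camera also rests on their few residual degrees of freedom. A call lost in that form therefore cannot be laid to correlation alone. No list passed by camera with an estimated correlation: adjusted p = 0.860 for this list and for the other 3 that camera called.

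Those 3 lists were extracellular proteolysis, cholesterol synthesis and uptake, and endoplasmic reticulum stress and heat shock. In extracellular proteolysis, 3 of 19 measured members rose, namely MMP9, the protease inhibitor TIMP2 (log2 ratio 2.68) and ADAMTS1, none fell, and adjusted over the list alone 12 were higher and 3 lower (camera adjusted p = 0.00561). In cholesterol synthesis and uptake, 6 of 20 rose, among them MVK (1.34), CYP51A1 (1.13, with 1 of 3 probes called) and DHCR7 (0.87), all enzymes of the sterol pathway, while HSD17B7 fell by 1.07 (camera adjusted p = 0.00909). Adjusted over the list alone, 7 were higher and 1 lower. MVK was measured by 3 probes, of which 1 had the opposite sign, and 5 of 18 alternatives that kept all replicates lost its call (adjusted p up to 0.130), as 5 of 18 did for HERPUD1 (up to 0.0748). In the stress list, 2 of 19 rose, the membrane protein HERPUD1 (1.48) and the chaperone HSPH1 (1.21), and adjusted over the list alone 10 were higher and 1 lower (camera adjusted p = 0.00561). Without replicate 3 the cholesterol list lost its camera call (adjusted p = 0.192). Unpaired, with no replicate block, the preranked form of camera did not call it either (adjusted p = 0.0928).

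In steroidogenesis 3 of 16 measured members rose and none fell. The lipoprotein receptor SCARB1 had a log2 ratio of 2.69 ± 0.50 (SD, n = 3), the side-chain cleavage enzyme CYP11A1 2.20 ± 0.22 and the progesterone receptor PGR 1.79 ± 0.22. Adjusted over the list alone, 4 were higher and 2 lower. STAR, which brings cholesterol into mitochondria, had a log2 ratio of 0.08 ± 0.90, with replicate values of 0.74, -0.94 and 0.45, and the aromatase CYP19A1 one of 0.02 ± 0.33. Among 19 genes of granulosa differentiation the inhibin subunit INHBB rose (2.30 ± 0.04) and the FSH receptor FSHR fell by 0.83 ± 0.28 (adjusted p = 0.0478), and adjusted over the list alone 4 were higher and 5 lower. The FSHR call was lost under 8 of 18 alternatives that kept all replicates (adjusted p from 0.00192 to 0.148). LHCGR, the luteinising hormone receptor, was not above the negative controls, and no probe named for EREG was found.

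Single members were called in lists that camera did not call. Over all 13134 named genes 8.73% were called, so 1 or 2 calls in a list do not set that list apart. Of the same genes 4051 had an unadjusted p under 0.05 in limma. A few calls adjusted over the list alone therefore do not set a list apart either. Among 12 hexosamine and hyaluronan precursor genes GFPT2, a rate-limiting hexosamine enzyme, rose (2.33) with HAS2, and UGP2 fell by 1.35. Adjusted over the list alone, 2 were higher and 3 lower. Of 20 glycolysis and glucose transport genes the hexokinase HK2 rose (2.55), and adjusted over the list alone 3 were higher and 5 lower. Of 15 hypoxia and angiogenesis genes FGF2 rose (2.50) and HIF1A fell by 1.07 by its brightest probe, which was saturated on 1 control array, its 3 probes ranging from -2.12 to -1.07, with 2 higher and 4 lower adjusted over the list alone. Of 13 gap junction and cGMP genes the connexin GJA5 rose (2.01), with 3 higher and 2 lower adjusted over the list alone. Of 15 prostaglandin genes PTGDS rose (1.26) and PLA2G4A fell by 0.90, with 1 higher and 2 lower adjusted over the list alone. Of the alternatives that kept all replicates, 7 of 18 lost the call of PLA2G4A (adjusted p up to 0.0887).

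Among 11 EGF-like ligand and receptor genes AREG rose and BTC fell, and adjusted over the list alone 2 were higher and 1 lower. Among 12 MAPK feedback genes DUSP5 rose (0.85) and SPRY1 fell by 1.02 (its other probe -0.0546 and not called), as they did adjusted over the list alone. Of 18 immediate early genes BTG2 rose (1.92), and adjusted over the list alone 3 were higher and 2 lower. Of 28 cell cycle genes RRM2 rose (1.31; its 4 probes from 0.0841 to 2.03, 2 of them called), also adjusted over the list alone; camera did not call the list (adjusted p = 0.224) but placed it lower without replicate 2 (adjusted p = 0.00154). Of 17 arrest and apoptosis genes the kinase inhibitor CDKN1A rose 2.83-fold and CASP8 fell by 1.76, with 2 higher and 3 lower adjusted over the list alone. Of 15 SMAD and TGF-beta genes ACTA2 (log2 ratio -1.29) and TGFB2 (-0.99) fell, with 4 higher and 4 lower adjusted over the list alone; 4 of 17 alternatives that kept all replicates lost the TGFB2 call (adjusted p up to 0.0718). Mean, median and camera direction differed in sign for the immediate early, hexosamine and glycolysis lists, and the steroidogenesis median was -0.00114 beside a mean of 0.23; camera called none of these lists.

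**Figure D2:**
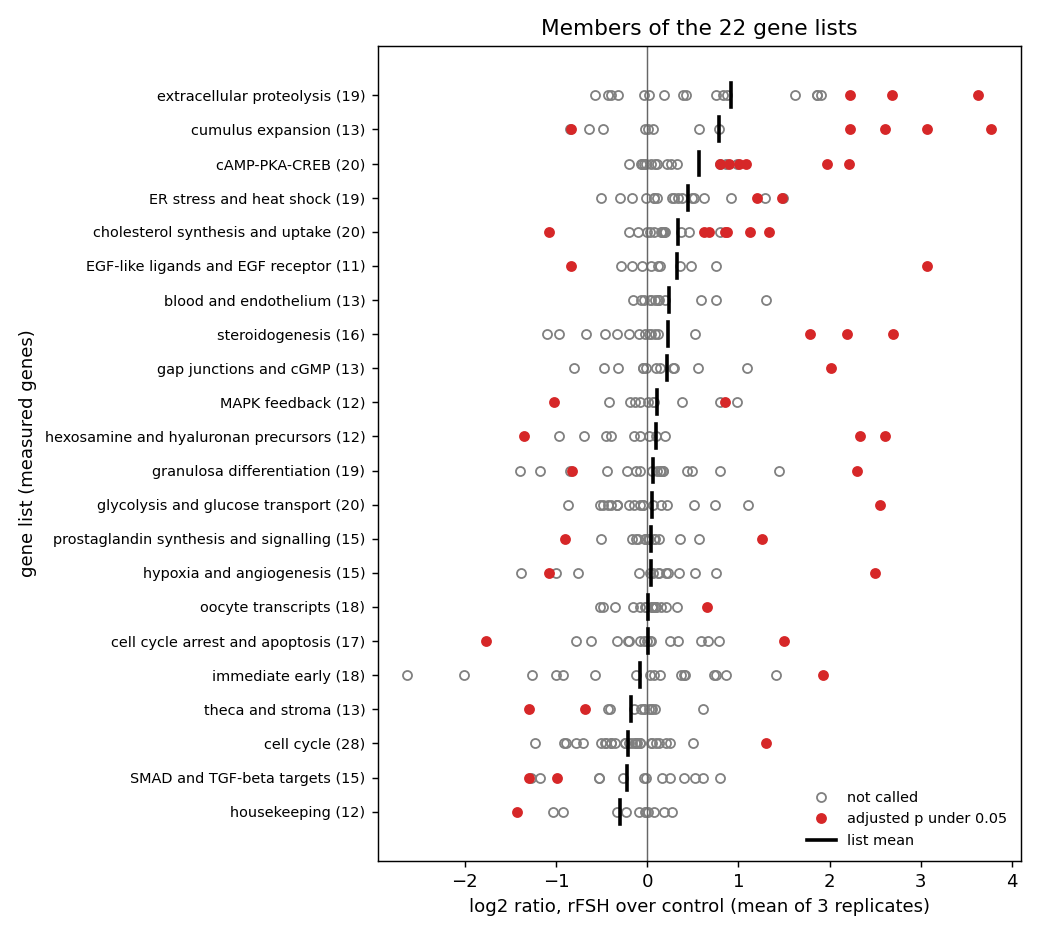
Log2 ratio of rFSH over control for each measured member of the 22 gene lists, 1 row per list with the number of measured genes in brackets. Filled points have an adjusted p under 0.05 in limma and black bars are list means, from 0.92 for extracellular proteolysis to -0.29 for the housekeeping list.

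Markers of other cells were examined because cumulus preparations can carry oocyte, theca or blood cells. Of 18 oocyte transcripts UCHL1 rose (0.66), 2 of its 3 probes having the opposite sign and 4 of 18 alternatives that kept all replicates losing its call (adjusted p up to 0.0796), and the list mean was 0.01 ± 0.92 (SD, n = 3), with 0.81 in replicate 2, -1.001 in replicate 3 and 0.24 in replicate 4. Camera did not call this list (adjusted p = 0.594), but called it without replicate 3 (adjusted p = 0.00247). That call used the preset correlation of 0.01, while the estimate over all replicates was 0.526 (camera adjusted p = 0.866). Of 13 theca and stroma genes ACTA2 fell, as did the smooth muscle myosin MYH11 (log2 ratio -0.68), which was not above the negative controls with rFSH on any array. Over the alternatives that kept all replicates, the MYH11 ratio ranged from -1.25 to -0.45. The latter was without background correction, where it lost the call. For the theca and stroma list adjusted over the list alone 1 was higher and 3 lower. None of 13 blood and endothelium genes was called in limma or adjusted over the list alone, and their mean log2 ratio was 0.24. Of 12 housekeeping genes B2M fell by 1.43, with 1 of its 2 probes of opposite sign, and adjusted over the list alone 2 were lower.

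Agreement between arrays was measured across probes, which are not independent replicates. Turned log2 ratios of dye-swapped arrays correlated at 0.494 to 0.722 (Pearson), replicate means at 0.617 to 0.709, and arrays of different replicates at 0.563 to 0.739 in the same dye orientation against 0.340 to 0.548 in the other. The lowest values between arrays, 0.494, 0.563 and 0.340, all involved the replicate 2 array with rFSH in Cy3. The other dye-swapped pairs lay at 0.722 and 0.707. That replicate 2 array also had the lowest detection, 38.3% of probes in its control channel. A gene-specific dye effect was called in limma for 1976 probes brighter in Cy5 and 2428 brighter in Cy3. It cancels where a replicate has a value in both orientations. ADAMTS1 had no value on the replicate 3 array with rFSH in Cy5, so its replicate 3 ratio rests on 1 orientation.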

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

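For 67 named genes and the 22 list means, the 6 turned array values were searched for a single array standing apart (Dixon's test), and of 88 sets with a value on every array 2 stood out where chance alone gives about 4.4. UGP2 had a log2 ratio of -2.13 on the array of replicate 4 with rFSH in Cy3, against -1.36 to -1.05 on the others. MYH11 had -0.27 on that same array, against -0.85 to -0.71 on the others. No explanation was tested for either.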

How the results depend on the processing

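The trimmed mean and median of pixels, the negative control background and leaving out the replicate 2 array with rFSH in Cy3, whose negative controls varied most, were alternatives chosen after seeing the data. No alternative called a probe in the direction opposite to the comparison reported, and no called gene or called list changed direction. Values near 0 that were not called did change sign: list means of oocyte transcripts under 9 alternatives, arrest and apoptosis under 5, glycolysis under 3 and hypoxia, granulosa differentiation and immediate early genes under 1 each, and the ratios of CYP19A1 and STAR under 6 and 5. Counts of higher and lower probes moved by over 1.5 times as follows, and the cause was not tested unless stated. They were 570 and 482 without background correction, and 2674 and 3381 with 6 arrays, a random replicate block and a dye term. Array weights on 6 arrays gave 3582 and 4474. That fit had no block, so the dye-swapped arrays of a replicate counted as independent, which overstates the number of replicates. Unpaired replicate values, with no replicate block, gave 468 and 558. Only arrays with rFSH in Cy5 gave 1566 and 1833, and only those with rFSH in Cy3 gave 1576 higher. Lower probes alone moved to 1863 with offset 0, 715 with plain subtraction, 1848 with median centring and 2011 with detection on every array, which tests fewer probes. By construction of the threshold, 475 and 575 were also at least 2-fold and 2330 and 2771 passed at 0.1. Leaving out each replicate gave 0 to 510 higher probes, 0 to 677 lower probes and 0 to 53 of the 63 called named genes, with fewer samples. Camera called 4 lists, and 0 with an estimated correlation, which also leaves it few degrees of freedom. The directional test of fry called 0, and its mixed test, which takes changes in either direction, called 19 of 22. Unlike camera, fry asks whether members changed, not whether they changed more than other genes. With 4051 of 13134 genes at an unadjusted p under 0.05 in limma, the mixed test passes easily. It called even the housekeeping list (fry mixed adjusted p = 0.0166), so the 19 calls do not mark lists that responded in particular. The preranked form of camera called steroidogenesis with the random block (adjusted p = 0.0394) and array weights (adjusted p = 0.0349), so there the set test differed too. Camera lost the stress list on arrays with rFSH in Cy5 (adjusted p = 0.0542). Over all settings, values of single named genes kept their call or lack of one 1253 times and lost a call 210 times. Aquantile changes no ratio by construction, and the authors' values gave 1029 and 944. Signal near the negative controls limits dim probes.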

Other observations

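All tests in this part were chosen after the result was seen. Interferon-stimulated genes were among the decreases but in no list fixed beforehand. Of 57 measured members of a list written after the first values were seen, 24 fell, none rose in limma, and 50 lay below 0. None of the 31 members not seen as called when the list was written was called. The 24 falls thus all come from members already seen, and their count is no support for the list. Log2 ratios were -2.86 for PARP9, -2.75 for HERC5, -2.21 for PARP12, -2.10 for PARP14, -1.63 for the antiviral GTPase MX1, -1.66 for the kinase EIF2AK2 and -1.14 for the transcription factor STAT2; these were named after their values were seen. The list mean was -1.11, -1.35 and -0.80 in replicates 2, 3 and 4.

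The dye part, the distance of the list mean with rFSH in Cy5 from the mean of both orientations, was 0.0245 ± 0.0270 (SE over 3 replicates). The list mean was -1.09. A dye effect cancels in a mean over both orientations by design, so the size of the dye part does not test the shift. It shows only that both orientations gave similar list means. The 31 interferon members not seen as called when the list was written had a mean of -0.49 ± 0.19 (SE over 3 replicates) but -0.11 in replicate 4. Their camera call (adjusted p = 0.00164) was lost with an estimated correlation (adjusted p = 0.542), a form with few degrees of freedom whose loss decides little. Given the spread over replicates, selection of genes already seen was not excluded. Blood and endothelium markers had a mean of 0.24 and a median of 0.12, but 1 of the 13 was above the negative controls in both channels of every array, so fewer leukocytes or endothelial cells cannot be told apart from other causes. Apart from these cell markers and the stromal markers given below, no biological explanation was tested for this list or the next 2. A difference in culture time between the groups stays open.

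Lists of actin-linked and of neurosecretory genes were written in the same way. In the first, 11 of 43 measured members fell and 1 rose, and in the second 17 of 46 rose and 1 fell. Among members not seen as called, 0 of 30 fell and 1 rose in the first list. In the second, 2 of 31 such members rose and 1 fell. The counts for the whole lists thus rest mostly on genes already seen as called and are no support for the lists. The dye parts were -0.0101 and 0.0164, beside list means of -0.58 and 0.87, and again do not test the shift. The members not seen as called had means of -0.0833 ± 0.0726 and 0.0610 ± 0.0806 (SE over genes), which decides nothing on selection, since leaving out called members moves a mean toward 0. The stromal markers COL1A1, COL3A1, DCN and LUM had a mean of -0.0446 ± 0.199 (SE over 3 replicates), a spread too wide to decide, so less stroma with rFSH cannot be told apart for the actin list.

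With 3 paired replicates there are 4 sign patterns, too few for a share under 0.05. The real one, 1 of the 4, called 2208 probes and the highest of the others called 0.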
